A study of Mus musculus with 18 samples.

How the data were processed

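The 18 libraries were made from sorted cells of cultured mouse kidneys, with poly(A) RNA capture and tagmentation from 100 to 300 ng of RNA, per the labels' protocols. Per the labels, cultures of a condition were pooled and digested for 30 minutes before the sort, and a replicate number marks a litter, so replicates came from separate litters. The authors deposited 1 table of 78409 genes with an estimated count and a CPM value for each library. Per the submitters' processing notes, the tools used upstream included fastp 0.24.0, STAR 2.7.11, featureCounts from Subread 2.1.1, SAMtools 1.22.1, FastQC 0.12.1 and MultiQC 1.32, with the genome build GRCm39. Their settings, the annotation and the use of strand are not given in the sources used here. The deposited counts are estimated counts that need not be whole, since 22.1 to 27.4% of the nonzero values in a library were fractions, and how multiply mapped reads were shared is not stated. The deposited CPM values equal the authors' counts divided by the library's sum and multiplied by 1e6, as checked on the table.

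From there, the counts were rounded to whole numbers, and the 92 spike-in transcripts of the ERCC set were left out, which leaves 78317 genes. Of these, 21909 have no symbol in the table and are not named. No column was left without a sample. Gene names and identifiers are those of the table, and no coordinates are given because the reference annotation at hand is of another build. Libraries were assigned to the 6 groups by their labels. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 16544 genes. Library sizes were scaled by TMM, and edgeR's quasi-likelihood test with robust dispersions was fitted to all 18 libraries with 1 mean per group, so that every comparison shared 1 estimate of the spread (12 residual degrees of freedom, common biological coefficient of variation 0.165). P-values were adjusted by Benjamini-Hochberg over all genes tested within each of 11 comparisons, with a threshold of 0.05. Every adjusted p of a single gene is from this edgeR test unless another tool is named. Intervals are 95% intervals from the fit. Means and SDs are of the deposited CPM. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

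Before the data were examined, 29 gene lists of kidney cell types and pathways, the tests and the other settings to be tried were fixed. The camera test of limma, with a preset correlation of 0.01, was applied to the 28 lists with at least 5 tested members, and its p-values were adjusted over the lists of a comparison. Each list was tested again with a correlation estimated from the data and with limma's fry, and members were counted over all genes and adjusted over the list alone. The lists share some members. Genes were named by a rule fixed at the same time. It takes the targeted genes, then the 8 highest and 8 lowest called genes by log2 fold change with at least 5 CPM on average and the same sign in all 3 litters (6 and 6 for interactions or over 300 calls), leaving out predicted genes and pseudogenes, then up to 4 members with the smallest p for each list that passed. Where fewer than 10 genes passed, genes were added up to 10 by unadjusted p. A selection of these is given in the text, and the genes named under other observations were chosen after their values were seen.

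The litter numbers were checked by correlating the libraries' deviations from their group means over genes. The 45 pairs of libraries from the same litter correlated with r = 0.237 to 0.639, and the 90 pairs from different litters with r = -0.544 to 0.310 (median -0.267), so the 2 ranges overlap. Litter was therefore also fitted as a block (common coefficient of variation 0.0987). Other alternatives were DESeq2's size factors in the same fit, DESeq2's own test, no filter on low counts, only the libraries of the compared groups, and leaving out each library in turn. Fits without litter 3 and with the culture as a block were added after seeing the data. Libraries of 1 group differed by a chi-square per gene of 4.29 to 51.9 over 18 pairs, above sampling noise in each, so none was treated as a duplicate.

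The median standard error of a log2 fold change was 0.198 for Mylk-shRNA against scramble-shRNA in the positive fraction (0.154 above 10 CPM) and 0.112 for the average of the fractions. The tests were tried on simulated counts with the real means and library sizes, 250 genes changed at each fold size over 5 simulations. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery at lower counts was not measured. For Mylk-shRNA against scramble-shRNA in the positive fraction the fit without a block recovered 0.8%, 20%, 70.8% and 96% of genes changed 1.25-, 1.5-, 2- and 3-fold, with no false call on average (0), and the fit with the block 8.8%, 58.4%, 91.2% and 99.6%, with 9.4 false calls per simulation. In the same simulations camera found a list of 20 genes changed 1.5-fold in 5 of 5 and called 1 of 100 unchanged lists. The lists held random genes, and each gene was drawn separately. The simulations therefore do not show how often the preset correlation gives false calls for lists of genes that vary together. For the shared scramble-shRNA controls, 30 simulations with no vector effect were run. Depth was tested by thinning each library to the same total in 3 random draws, and other splits of the libraries were counted, all splits or 100 drawn at random.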

Results

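Bulk RNA sequencing was carried out on kidneys of wild-type CD1 mice, an outbred stock, taken at embryonic day 14 and cultured as explants. The series concerns how nephrons, the filtering units of the kidney, form in the developing organ. The kidneys were transduced for 4 hours with AAV2, an adeno-associated virus used for gene delivery, and then kept for 72 hours in a 3D gel. Each vector carried the red fluorescent reporter mCherry and 2 short hairpin RNA (shRNA) cassettes, which lower a target transcript through RNA interference. The cassettes were directed against separate regions of Mylk (Mylk-shRNA) or against Rock1 and Rock2 (Rock1/2-shRNA), or held shuffled Rock1 and Rock2 target sequences as a control (scramble-shRNA). Mylk encodes myosin light chain kinase, and Rock1 and Rock2 encode kinases that drive actomyosin contraction. Cells were sorted into a positive fraction, the top 25% of mCherry signal, and a negative fraction, the bottom 50%. Each of the 6 groups of vector and fraction held 3 libraries, 1 from each of 3 litters, so the spread between replicates was that between litters. Total counts ranged from 3121616 to 12170814 per library, with a median of 7581371. In all, 16544 genes were tested.

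The first principal component of log2 CPM (the count scaled by the library's total) held 40.01% of the variance and parted the positive from the negative fractions, while the second, with 21.5%, set the libraries of litter 3 apart from the others. Mitochondrially encoded genes took 6.68% ± 1.73 of the counts in litter 3 (SD, n = 6) and 3.02% ± 0.577 in litters 1 and 2 (SD, n = 12). The litter 3 libraries also held fewer counts, 4368740 ± 1378473 against 8820834 ± 3087210.

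**Figure D1:**
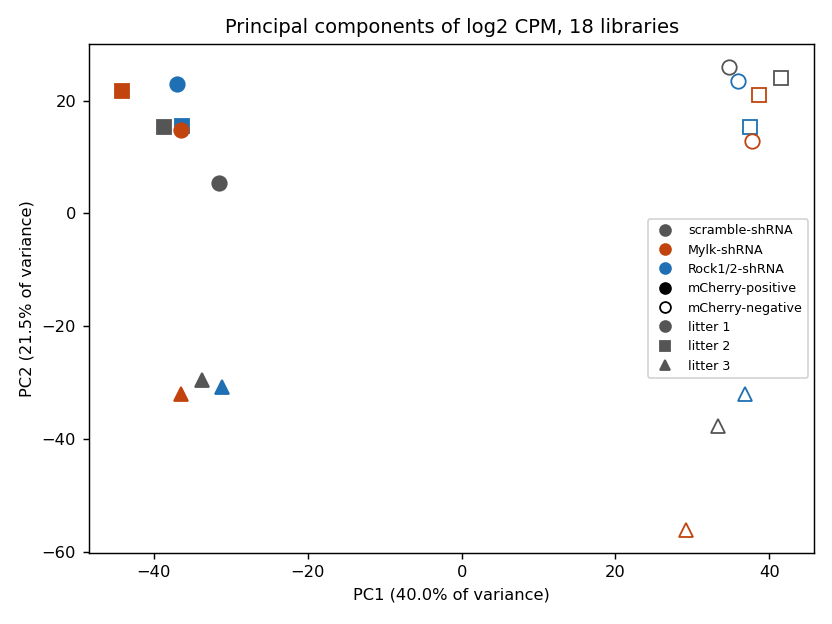
Principal components of log2 CPM for the 18 libraries, with the first component (40.01% of the variance) on the x axis and the second (21.5%) on the y axis; colours give the vector, filled and open symbols the positive and negative fractions, and symbol shapes the litter. The fractions lie at opposite ends of the x axis, and the 6 libraries of litter 3 have the lowest values on the y axis.

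The targeted transcripts were measured first in every group. In the positive fraction Mylk (ENSMUSG00000022836) stood at 175 ± 10.7 CPM with Mylk-shRNA and 197 ± 14.7 CPM with scramble-shRNA (SD, n = 3 each), which is 87.9% of scramble (95% interval 71.3 to 108%). Rock1 (ENSMUSG00000024290) stood at 80.2 ± 4.90 against 85.6 ± 13.7 CPM with Rock1/2-shRNA and scramble-shRNA, or 94.1% of scramble (95% interval 76.7 to 115%). Rock2 (ENSMUSG00000020580) stood at 62.9 ± 6.02 against 71.4 ± 9.12 CPM, or 88.7% of scramble (95% interval 70.8 to 111%). In the negative fraction the same ratios were 106% of scramble (95% interval 86.0 to 132%) for Mylk, 88.0% of scramble (95% interval 72.0 to 107%) for Rock1 and 94.5% of scramble (95% interval 76.0 to 118%) for Rock2. Each of these intervals includes 100%. The means of Mylk in the positive fraction lay further apart than either SD, and with the mean of the smooth muscle genes as a covariate, without an adjustment over genes, the interval was 74.2 to 99.4% of scramble (estimate 85.9%). By litter, however, Mylk was lower with Mylk-shRNA than with scramble-shRNA in litters 1 (169 against 211 CPM) and 3 (168 against 198 CPM) but higher in litter 2 (187 against 181 CPM). In the positive fraction 2-sided exact permutation tests, which did not pair libraries by litter, gave p = 0.2 for Mylk, 0.8 for Rock1 and 0.4 for Rock2, where 3 libraries against 3 cannot go below 0.1. edgeR's quasi-likelihood test adjusted over the list alone of the 3 targeted genes gave 0.627, 0.541 and 0.541. Leaving out litter 3, or scramble-shRNA positive replicate 3 alone, turned the log2 fold change of Rock1 in the positive fraction from -0.09 to 0.079 and 0.052. In the negative fraction that of Mylk turned from 0.09 to -0.041 without Mylk-shRNA negative replicate 3 and -0.034 without scramble-shRNA negative replicate 2, and that of Rock2 from -0.08 to 0.0075 without scramble-shRNA negative replicate 1. The counts are per gene and do not separate transcript isoforms, and they say nothing of protein.

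**Figure D2:**
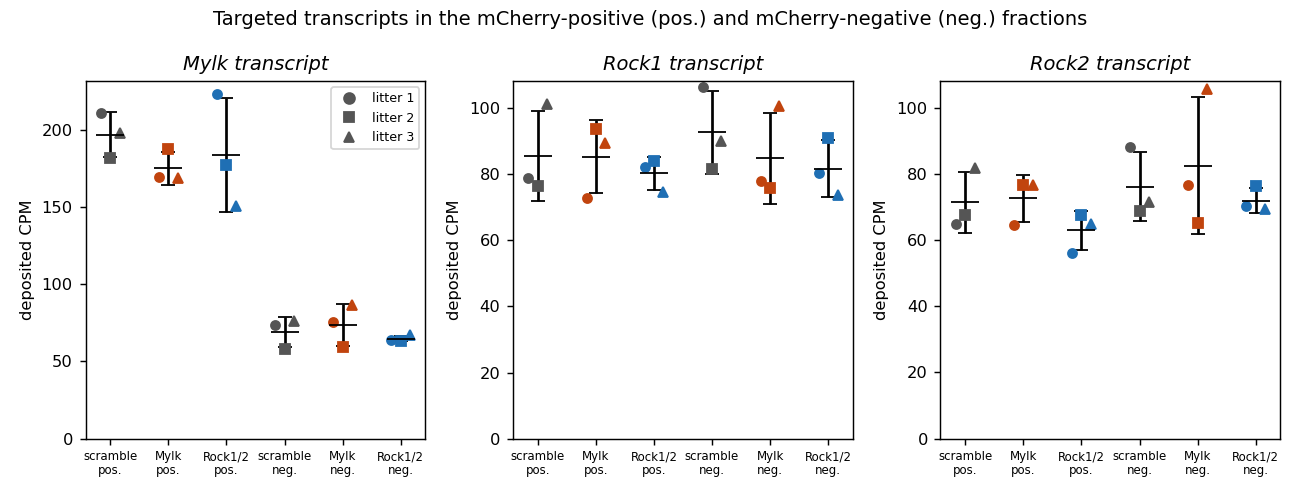
Deposited CPM of Mylk, Rock1 and Rock2 on the y axes for the 6 groups of vector and fraction on the x axes; each symbol is a library, its shape gives the litter, and bars show the mean ± SD of 3 libraries. Mylk is higher in the positive fraction with every vector, at 185 against 69.1 CPM on average.

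The effect of Mylk-shRNA was asked in the positive fraction against scramble-shRNA. No single gene passed the test. Among genes that met the naming rule, the smallest p-values belonged to Zfp790, a zinc finger gene, at 6.73 ± 1.01 against 3.71 ± 0.472 CPM, and Calcrl, which encodes the receptor of adrenomedullin, at 36.6 ± 7.001 against 24.8 ± 3.51 CPM (SD, n = 3 each). Next came Tifa, an adaptor in NF-kB signalling (log2 fold change 0.44 ± 0.13, SE), Dnajb5, a heat shock co-chaperone (0.55 ± 0.18), and Zfp830 (-0.45 ± 0.15), each with the same sign in the 3 litters and adjusted p = 1.00. Among the gene lists, cytosolic ribosomal proteins lay lower than other genes with a median log2 fold change of -0.20, and only 3 of 94 members had a positive value (camera, adjusted p = 9.97e-14). Interstitial stroma, the connective tissue between the tubules, lay higher, with 16 of 18 members positive and a median of 0.12 (adjusted p = 0.000927), led by the mesenchymal transcription factor Tbx18 (0.44 ± 0.18), the matrix genes Postn (0.31 ± 0.16) and Col3a1 (0.25 ± 0.13), and the growth factor receptor Pdgfrb (0.27 ± 0.15). Focal adhesion and extracellular matrix genes lay slightly higher (median 0.09, adjusted p = 0.0449) and cell cycle genes slightly lower (median -0.07, adjusted p = 0.0444). All 4 calls were lost with an estimated correlation between genes (adjusted p = 0.993 each), and no member passed singly, over all genes or adjusted over the list alone. Without litter 3 the cell cycle call was lost too (adjusted p = 0.0626). The focal adhesion and cell cycle calls were lost in 3 of 6 fits with 1 library left out and the ribosomal call in 1 (adjusted p up to 0.929, 0.959 and 0.0647). With litter as a block, proximal tubule genes also lay lower (median -0.22, adjusted p = 0.0185 against 0.0873 without it). That call was lost with an estimated correlation in the blocked fit (0.935).

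The count of genes passing edgeR's test at an adjusted p under 0.05 was 0 of 16544, with 258 at an unadjusted p under 0.05 (1.56%), and DESeq2 also called 0, with 154 at an unadjusted p under 0.05. The counts simulated for this comparison changed only genes with a mean of at least 5 CPM. Of those changed 2-fold the test recovered 70.8%, and of those changed 1.5-fold 20%. With litter as a block it recovered 91.2% and 58.4%, with 9.4 false calls per simulation, and on the real counts that fit also called 0 genes.

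Rock1/2-shRNA was set against scramble-shRNA in the same fraction. The Rock1/2-shRNA cultures also differed from the others in Y-linked transcripts in each litter, as given under other observations. The comparison does not separate that difference from the vector. Among genes that met the naming rule, the smallest p-values were those of Znrf3, which encodes a ubiquitin ligase that removes Wnt receptors, at 14.2 ± 0.743 against 9.59 ± 1.13 CPM, and Lrrc8b, a subunit of the volume-regulated anion channel, at 28.9 ± 1.07 against 20.1 ± 1.46 CPM (SD, n = 3 each). Calcrl (log2 fold change 0.44 ± 0.14, SE), Zfand4 (0.61 ± 0.21), Dnajb5 (0.56 ± 0.18) and Gprc5b (-0.52 ± 0.19) followed, and none of these passed over all genes (adjusted p = 1.00). Znrf3 was the only member of any list to pass when adjusted over the list alone, in a list of Wnt and beta-catenin targets that as a whole did not pass (adjusted p = 0.172). Endothelial genes lay lower (median -0.22, 2 of 16 members positive, adjusted p = 0.000306), among them Plvap (-0.32 ± 0.15), the transcription factor gene Sox18 (-0.38 ± 0.23) and the junctional cadherin Cdh5 (-0.28 ± 0.24). Erythroid genes lay lower as well (median -0.82, 2 of 8 positive, adjusted p = 0.000994), with the globin gene Hbb-bt at 38.0 ± 25.6 against 75.8 ± 40.9 CPM. Cytosolic ribosomal proteins shifted less (median -0.05, adjusted p = 0.0424). Smaller shifts were also found for early nephron genes (median -0.14, adjusted p = 0.0453), such as the signalling factor Bmp2 (-0.32 ± 0.18), and actomyosin genes (median -0.07, adjusted p = 0.0453), such as the LIM kinase gene Limk2 (-0.27 ± 0.13). With an estimated correlation these calls were lost (adjusted p = 0.932 for endothelium, erythroid and actomyosin genes and 0.979 for the others). With litter as a block the early nephron and actomyosin calls were lost too (adjusted p = 0.0518 and 0.0871), as they were without litter 3 (0.583 and 0.533). Leaving out 1 library ended the calls in 5 of 6 fits for actomyosin, 4 for early nephron, 3 each for erythroid and ribosomal and 2 for endothelial genes (adjusted p up to 0.558, 0.704, 0.377, 0.947 and 0.253). The medians of early nephron and ribosomal genes were -0.024 and -0.093 without litter 3. The median of the ribosomal genes turned to 0.044 without scramble-shRNA positive replicate 3 and to 0.0052 and 0.0073 without Rock1/2-shRNA positive replicates 1 and 2, so 3 of the 6 fits with 1 library left out turned it.

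No gene passed edgeR's test (0 of 16544, with 145 at an unadjusted p under 0.05), and DESeq2 called 0, with 79. Hbb-bt varied widely between the libraries of a group, as its SDs show, and reads of near-identical globin copies may be shared in the deposited counts.

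Mylk-shRNA and Rock1/2-shRNA were also set against each other in the positive fraction. Tbx18 stood at 37.3 ± 6.54 against 25.9 ± 6.399 CPM and the potassium channel gene Kcnk2 at 13.1 ± 0.658 against 8.63 ± 1.29 CPM with Mylk-shRNA and Rock1/2-shRNA (SD, n = 3 each), while Spag7 stood at 56.1 ± 6.29 against 72.9 ± 3.84 CPM and the histone methyltransferase gene Setmar at 4.24 ± 1.19 against 6.86 ± 0.656 CPM. None passed over all genes (adjusted p = 1.00). Stroma (median 0.13, adjusted p = 2.50e-05), smooth muscle, pericyte and renin cell genes (0.22, 0.000380) and endothelial genes (0.22, 0.00259) lay higher with Mylk-shRNA than with Rock1/2-shRNA. Examples were the smooth muscle myosin gene Myh11 (0.95 ± 0.47, SE), Notch3 (0.22 ± 0.13) and Postn (0.37 ± 0.16). Focal adhesion and matrix genes (median 0.13, adjusted p = 0.00114), the Notch pathway (0.19, 0.00126), cytoskeletal targets of the transcription factors MRTF and SRF (0.13, 0.00237), erythroid (0.46, 0.0188), actomyosin (0.06, 0.0266) and interferon response genes (0.14, 0.0459) lay higher too. Cytosolic ribosomal proteins (-0.13, 2.28e-07) and cell cycle genes (-0.11, 0.00722) lay lower. All 11 calls were lost with an estimated correlation (adjusted p = 0.603 to 0.702), and no member passed adjusted over the list alone. Without litter 3 the endothelial and actomyosin calls were lost too (adjusted p = 0.0807 and 0.131). There the medians of endothelial (0.12), MRTF and SRF (0.077), Notch (0.13), erythroid (0.92) and interferon genes (0.25) moved over 1.5 times. Each call was lost in some of 6 fits with 1 library left out: 4 for erythroid, actomyosin and interferon genes, 3 for endothelial and cell cycle genes, 2 for MRTF and SRF targets, focal adhesion, Notch and ribosomal genes, and 1 for stroma and smooth muscle (adjusted p up to 0.0563 to 0.995). The erythroid and cell cycle medians turned to -0.20 and 0.0052 without Mylk-shRNA positive replicate 3, and the ribosomal one to 0.0095 without Rock1/2-shRNA positive replicate 3. Blocking on litter added proximal tubule (median -0.24, adjusted p = 0.0184) and macrophage genes (0.13, 0.0209), both lost with an estimated correlation in that fit (0.596 and 0.489). edgeR called 0 genes, with 199 at an unadjusted p under 0.05, and DESeq2 called 0, with 100.

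Because both knockdowns were compared with the same 3 scramble-shRNA libraries, their fold changes shared chance values. Across genes, which are not independent replicates, the log2 fold changes of Mylk-shRNA and Rock1/2-shRNA correlated with r = 0.505, and 66.3% had the same sign. In 30 simulations with no vector effect the mean r was 0.494 (0.470 to 0.523) and the same-sign share 66.3%. The observed covariance of 0.0414 lay within the simulated range of 0.0376 to 0.0464. No gene was called in both knockdowns (edgeR called 0 in each, so independent lists would share 0, and DESeq2 called 0 as well), with 258 and 145 genes at an unadjusted p under 0.05. The 3 control libraries were too few to be split.

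In the negative fraction, which received the vector but showed little reporter signal, Mylk-shRNA was compared with scramble-shRNA. Fancm, a DNA helicase gene of the Fanconi anaemia pathway, stood at 9.54 ± 0.384 against 13.9 ± 1.71 CPM, the major histocompatibility gene H2-D1 at 58.6 ± 6.67 against 42.8 ± 7.27 CPM and the neuropeptide gene Nts at 18.7 ± 5.46 against 10.6 ± 1.27 CPM (SD, n = 3 each). None passed over all genes (adjusted p = 1.00). Endothelial genes lay higher, with 15 of 16 members positive and a median of 0.38 (adjusted p = 2.52e-08), among them Sox18 (0.51 ± 0.20, SE) and Cdh5 (0.48 ± 0.23). Nephron progenitor genes lay lower, with 1 of 15 positive and a median of -0.25 (adjusted p = 1.09e-07), among them Eya1 (-0.41 ± 0.18), a transcriptional regulator that maintains the progenitors, and Spock2 (-0.33 ± 0.11). Ureteric bud tip genes (-0.17, 0.00919) and cell cycle genes (-0.12, 0.00568) lay lower and hypoxia and glycolysis genes higher (0.10, 0.0154). With an estimated correlation the adjusted p was 0.479 for endothelium and nephron progenitors, 0.544 for ureteric bud tip and 0.983 for the others, so no call held, and no member passed adjusted over the list alone. The ureteric bud tip and cell cycle calls were lost without litter 3 as well (adjusted p = 0.116 and 0.0613), and the cell cycle median turned to 0.049 without Mylk-shRNA negative replicate 3. With 1 library left out the calls were lost in 4 of 6 fits for hypoxia, 3 for cell cycle, 2 for ureteric bud tip and 1 for nephron progenitor genes (adjusted p up to 0.939, 0.701, 0.428 and 0.208), and in none for endothelial genes. The cell cycle median without litter 3 was -0.073. Blocking on litter added immediate early and dissociation stress genes (median 0.17, adjusted p = 0.00735), lost with an estimated correlation in that fit (0.984). edgeR called 0 genes, with 285 at an unadjusted p under 0.05, and DESeq2 called 0, with 219.

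With Rock1/2-shRNA in the negative fraction, H2-D1 stood at 57.5 ± 4.33 against 42.8 ± 7.27 CPM, Ppp1r14a, an inhibitor of myosin phosphatase, at 47.7 ± 2.12 against 36.1 ± 5.19 CPM and Atad5, a gene of DNA replication, at 19.2 ± 0.910 against 25.9 ± 1.322 CPM (SD, n = 3 each). None passed over all genes (adjusted p = 1.00). Cytosolic ribosomal proteins lay higher (86 of 94 positive, median 0.11, adjusted p = 5.20e-05), as did erythroid (8 of 8, 0.81, 0.000830), hypoxia and glycolysis (19 of 19, 0.12, 0.00131), endothelial (16 of 16, 0.18, 0.00131) and proximal tubule genes (14 of 14, 0.25, 0.0192). Examples were Hbb-bt (1.43 ± 0.64, SE), the carbonic anhydrase gene Car9 (0.45 ± 0.22), the endothelial transcription factor gene Sox17 (0.57 ± 0.30) and the endocytic receptor gene Lrp2 (0.35 ± 0.30). Nephron progenitor genes lay lower (1 of 15 positive, -0.11, 0.0208) and epithelial junction genes higher (0.12, 0.0242). No list held with an estimated correlation (adjusted p = 0.964 each), and no member passed adjusted over the list alone. The epithelial junction call was lost without litter 3 as well (adjusted p = 0.528). Its median turned to -0.13 without Rock1/2-shRNA negative replicate 2 and -0.12 without scramble-shRNA negative replicate 3, and that of the ribosomal genes to -0.042 without scramble-shRNA negative replicate 1. Leaving out 1 library ended the calls in 4 of 6 fits for nephron progenitor, 3 each for proximal tubule and hypoxia, 2 each for endothelial, epithelial junction and ribosomal genes and 1 for erythroid genes (adjusted p up to 0.186 to 0.612). The medians of proximal tubule and endothelial genes were 0.41 and 0.11 without litter 3. Blocking on litter added stroma (median -0.09, adjusted p = 0.0402), lost with an estimated correlation in that fit (0.853). edgeR called 0 genes, with 200 at an unadjusted p under 0.05, and DESeq2 called 0, with 152. Near-identical gene copies, as among the globin and histocompatibility genes, make the values of H2-D1 and Hbb-bt uncertain. Both comparisons in the negative fraction used the same 3 scramble-shRNA libraries. A shared direction, as for H2-D1 and for endothelial, hypoxia and nephron progenitor genes, can thus arise without an effect of either vector, and their agreement was not tested.

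Whether a knockdown acted differently in the positive fraction was tested as an interaction, the knockdown effect in the positive minus that in the negative fraction. For Mylk the difference was -0.28 ± 0.21 with Mylk-shRNA (log2, SE). For Rock1 and Rock2 it was 0.10 ± 0.20 and -0.09 ± 0.22 with Rock1/2-shRNA, the latter turning to 0.022 without scramble-shRNA positive replicate 3. None passed. With Mylk-shRNA, Dnajb5 (0.85 ± 0.25), the fibroblast growth factor antagonist Spry2 (0.47 ± 0.16) and Zfp57 (-1.26 ± 0.41), a zinc finger gene of genomic imprinting, had some of the smallest p-values, none passing over all genes. With Rock1/2-shRNA these were the retinol binding protein gene Rbp4 (-1.02 ± 0.30), Nudt14 (-1.0024 ± 0.30) and Znrf3 (0.65 ± 0.19). Both interactions subtract the same 6 scramble-shRNA libraries, so a shared sign is expected without an effect of either vector, and their agreement was not tested. Endothelial genes had a median interaction of -0.41 for Mylk-shRNA (adjusted p = 3.22e-05) and -0.49 for Rock1/2-shRNA (adjusted p = 1.38e-07), as in Plvap (-0.44 ± 0.21 and -0.50 ± 0.21). For cytosolic ribosomal proteins these were -0.23 (2.88e-09) and -0.17 (2.46e-07). Mylk-shRNA gave proximal tubule genes a negative (-0.51, 0.00955) and nephron progenitor genes a positive median (0.17, 0.0134). Rock1/2-shRNA gave erythroid genes a negative (-1.64, 1.38e-07) and Wnt targets a positive median (0.11, 0.0458). With an estimated correlation no call held (adjusted p = 0.967 for Mylk-shRNA and 0.418 to 0.965 for Rock1/2-shRNA), and no member passed adjusted over the list alone. Without litter 3 the nephron progenitor and proximal tubule calls of Mylk-shRNA (adjusted p = 0.166 and 0.137) and the Wnt call of Rock1/2-shRNA (0.295) were lost. Their medians there were 0.10, -0.30 and 0.033, while that of the ribosomal proteins with Mylk-shRNA was -0.47 and that of endothelial genes with Rock1/2-shRNA -0.32. With 1 library left out the calls of Mylk-shRNA were lost in 5 of 12 fits for nephron progenitor, 4 for proximal tubule and 1 for ribosomal genes (adjusted p up to 0.919, 0.545 and 0.252). Those of Rock1/2-shRNA were lost in 8 for Wnt targets and 2 for ribosomal genes (0.208 and 0.983), and the endothelial and erythroid calls in none. Blocking on litter added hypoxia genes for both (adjusted p = 0.0117 and 0.0234), immediate early genes for Mylk-shRNA (0.0117) and proximal tubule genes for Rock1/2-shRNA (0.0380), all lost with an estimated correlation in that fit (0.899 for Mylk-shRNA, and 0.835 and 0.891 for Rock1/2-shRNA). edgeR called 0 genes in each interaction, with 217 and 145 at an unadjusted p under 0.05, and DESeq2 called 0, with 138 and 90.

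The positive and negative fractions were then compared, averaged over the 3 vectors. Transcripts of macrophages and other leukocytes rose most: 14 of 15 members passed in the positive fraction (14 adjusted over the list alone), with a median log2 fold change of 4.52 (adjusted p = 9.71e-65, and 0.00111 with an estimated correlation). C1qc, a chain of the complement protein C1q made by tissue macrophages, stood at 77.7 ± 18.9 against 0.913 ± 0.474 CPM in the positive and negative fraction (SD, n = 9 each; log2 fold change 6.53 ± 0.22, SE; adjusted p = 9.49e-13). C1qb (6.30 ± 0.25), C1qa (6.29 ± 0.30), the complement receptor gene C3ar1 (6.53 ± 0.31) and Gpnmb, a glycoprotein of phagocytes (6.60 ± 0.30; 172 ± 59.1 against 1.64 ± 1.01 CPM), were likewise among the 6 genes with the highest fold changes, in the same direction in each of the 3 litters. The signalling adaptors Fcer1g and Tyrobp rose by 4.67 and 4.69. Erythroid genes rose in 7 of 8 cases (7 adjusted over the list alone; median 2.22, adjusted p = 0.000481, and 0.183 with an estimated correlation), with the embryonic globin genes Hba-x at 144 ± 128 against 1.61 ± 1.11 CPM and Hbb-y at 416 ± 379.6 against 6.69 ± 3.65 CPM, SDs close to the means.

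Most stromal and smooth muscle genes rose in the positive fraction. Of 18 stroma genes 16 rose and none fell (16 rose and 1 fell adjusted over the list alone), with a median of 0.77 (adjusted p = 4.50e-25, and 0.00175 with an estimated correlation). The matrix proteoglycan genes Dcn and Lum stood at 282 ± 51.1 against 24.6 ± 5.43 and 68.9 ± 18.5 against 3.71 ± 0.748 CPM, and Foxd1, the transcription factor of the cortical stroma, at 327 ± 70.2 against 116 ± 16.3 CPM (SD, n = 9 each). Smooth muscle, pericyte and renin cell genes rose in 12 of 14 cases and fell in 1, also adjusted over the list alone (median 1.3201, adjusted p = 1.93e-07, and 0.0798 with an estimated correlation). Among them were the smooth muscle actin gene Acta2 at 403 ± 155 against 86.3 ± 17.9 CPM, Myh11 (3.00 ± 0.32, log2, SE) and Akr1b7 (2.67 ± 0.23), a marker of renin cells. Cytoskeletal targets of MRTF and SRF rose in 17 of 23 cases (18 adjusted over the list alone; median 0.53, adjusted p = 1.90e-12, and 0.0426 with an estimated correlation, or 0.0805 with litter as a block). Mylk belongs to that list and to the actomyosin list and was itself higher in the positive fraction, at 185 ± 22.5 against 69.1 ± 9.31 CPM (1.37 ± 0.08; adjusted p = 6.24e-10), as were Myl9 (1.94 ± 0.16), Actn1 (0.77 ± 0.06) and Tpm1 (0.82 ± 0.08). Of 30 actomyosin genes 9 rose and 2 fell, also adjusted over the list alone (median 0.14, adjusted p = 0.0113, and 0.183 with an estimated correlation). Rock1 (-0.10 ± 0.08) and Rock2 (-0.21 ± 0.09) did not pass (adjusted p = 0.377 and 0.0763), though Rock2 did with litter as a block (0.0199) and without litter 3, scramble-shRNA positive replicate 3 or Mylk-shRNA negative replicate 2. Targets of YAP and TEAD, which respond to cell tension, rose in 9 of 21 cases and fell in 4 (10 and 5 adjusted over the list alone; median 0.20, adjusted p = 0.00554, and 0.145 with an estimated correlation), with Ccdc80 (1.42 ± 0.09) and Tgfb2 (1.26 ± 0.08) leading. The median of these targets was 0.33 without litter 3.

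Most early nephron, nephron progenitor and epithelial junction genes fell in the positive fraction. Early nephron genes, which mark the pretubular aggregate to the S-shaped body, fell in 17 of 20 cases and rose in 2, also adjusted over the list alone (median -1.42, adjusted p = 1.44e-12, and 0.135 with an estimated correlation). Wnt4, the signal that starts the conversion of progenitors into epithelium, stood at 109 ± 12.1 against 345 ± 52.7 CPM. The nephron transcription factor gene Lhx1 stood at 5.50 ± 2.22 against 36.9 ± 17.8 CPM (SD, n = 9 each). Their log2 fold changes were -1.71 ± 0.09 and -2.83 ± 0.35 (SE). The Notch ligand gene Dll1 fell by 2.51 on the log2 scale. Nephron progenitor genes fell in 11 of 15 cases and rose in 1, also adjusted over the list alone (median -0.56, adjusted p = 2.08e-05, and 0.183 with an estimated correlation), with Eya1 at -0.80 ± 0.10, Uncx at -1.08 ± 0.13 and the integrin gene Itga8 at -0.48 ± 0.06. Epithelial junction and polarity genes fell in 19 of 20 cases, also adjusted over the list alone (median -1.40, adjusted p = 4.73e-10, and 0.158 with an estimated correlation), such as the protease inhibitor gene Spint2 at 37.0 ± 6.70 against 117 ± 35.6 CPM and the tight junction gene Ocln (-1.48 ± 0.20). Ureteric bud tip genes fell in 10 of 14 cases and rose in 2, also adjusted over the list alone (median -0.58, adjusted p = 0.000775, and 0.135 with an estimated correlation), with the receptor gene Ret at -1.48 ± 0.24 and Wnt11 at -1.01 ± 0.09, while Adamts18 rose (1.34 ± 0.20). Ureteric trunk and collecting duct genes fell in 8 of 12 cases (9 adjusted over the list alone) and rose in 1 (median -0.53, adjusted p = 0.00799, and 0.259 with an estimated correlation), the riser being Gata2 (0.96 ± 0.19). Proximal tubule genes passed as higher (median 0.23, adjusted p = 0.0234, and 0.570 with an estimated correlation), but singly only Apoe rose (409.6 ± 61.2 against 37.3 ± 5.29 CPM), a lipoprotein gene that macrophages also express strongly, and 2 fell, among them Hnf4a (-0.85 ± 0.27; same counts adjusted over the list alone). Hnf4a was no longer called without scramble-shRNA negative replicate 1, Rock1/2-shRNA positive replicate 2 or Mylk-shRNA negative replicate 1 (adjusted p = 0.0508, 0.0575 and 0.0608). Without litter 3 the proximal tubule list was no longer called (median 0.10, adjusted p = 0.172), nor was it in 6 of 18 fits with 1 library left out (adjusted p up to 0.0811). Endothelial genes fell in 9 of 16 cases (11 adjusted over the list alone) and rose in 3 (median -0.54, adjusted p = 0.00347, and 0.385 with an estimated correlation). Among them were Cldn5 (-1.52 ± 0.17) and the vascular growth factor receptor gene Flt1 (-1.24 ± 0.21). Within single vectors the endothelial list passed with Mylk-shRNA and Rock1/2-shRNA but not with scramble-shRNA.

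Metabolic and stress genes also parted the fractions. All 19 hypoxia and glycolysis genes fell in the positive fraction, also adjusted over the list alone (median -0.94, adjusted p = 1.35e-21, and 0.0549 with an estimated correlation, or 0.00101 with litter as a block), including Car9 at 2.69 ± 1.04 against 14.7 ± 3.25 CPM and the glycolytic enzyme gene Pgk1 at 321 ± 30.8 against 681 ± 95.2 CPM (SD, n = 9 each). Genes of the unfolded protein and integrated stress response fell in 15 of 18 cases (17 adjusted over the list alone; median -0.43, adjusted p = 3.52e-07, and 0.0193 with an estimated correlation, or 0.0535 with litter as a block), with Trib3 at -1.85 ± 0.17 and Ddit3 at -0.84 ± 0.09 (log2, SE). Wnt and beta-catenin targets, which share Wnt4 and Ccnd1 with the early nephron list, fell in 12 of 17 cases and rose in 1, also adjusted over the list alone (median -0.52, adjusted p = 1.99e-07, and 0.0178 with an estimated correlation, or 0.0708 with litter as a block), with Axin2 at -0.65 ± 0.06 and Tcf7 at -0.87 ± 0.08. Interferon response genes rose in 12 of 20 cases (14 adjusted over the list alone; median 0.74, adjusted p = 4.06e-06, and 0.135 with an estimated correlation), such as the RNA sensor gene Ifih1 (1.59 ± 0.18) and Ifit3 (1.85 ± 0.22). Cell cycle genes rose in 11 of 25 cases (12 adjusted over the list alone; median 0.27, adjusted p = 0.00339, and 0.619 with an estimated correlation), such as the mitotic kinase gene Plk1 (0.65 ± 0.12) and Ccne1 (0.60 ± 0.07). Cytosolic ribosomal proteins fell in 21 of 94 cases (16 adjusted over the list alone; median -0.23, adjusted p = 0.000163, and 0.680 with an estimated correlation), such as Rpl22 (-0.44 ± 0.09). Across all genes 2649 of 16544 fell, and the ribosomal list did not pass within scramble-shRNA. Outside the lists, the lowest fold change among genes that met the naming rule was that of Gpr15lg, which encodes a secreted ligand of the receptor GPR15, at 1.80 ± 0.546 against 27.2 ± 4.19 CPM. Large falls were also found in Derl3 (-2.70 ± 0.27), Clec18a (-2.60 ± 0.21) and the protease inhibitor gene A2m (-2.52 ± 0.16).

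The other lists did not pass. Focal adhesion and matrix genes rose in 10 of 23 cases and fell in 4 (the same adjusted over the list alone; adjusted p = 0.155), Notch pathway genes rose in 4 of 14 and fell in 6 (5 and 6 adjusted over the list alone; 0.703), and p53 targets rose in 6 of 21 and fell in 7 (7 and 7; 0.776). Podocyte genes rose in 3 of 11 cases and fell in 4 (4 and 4 adjusted over the list alone; 0.475), with a median of 0.29 but a mean of -0.12 and a downward test. Immediate early and dissociation stress genes rose in 2 of 20 cases and fell in 3 (the same adjusted over the list alone; 0.776), and here too the median of 0.14 and the downward test differed in sign. Loop of Henle and distal tubule genes rose in 1 of 10 cases and fell in 2 (1 and 4 adjusted over the list alone; 0.724), and 1 of 12 genes of the microRNA machinery, on which shRNA processing depends, fell (1 adjusted over the list alone; 0.758). None of the 29 mitochondrially encoded genes passed by edgeR, over all genes or adjusted over the list alone (median -0.33, adjusted p = 0.244). Of the neural crest, glia and neuron genes only 4 were expressed, too few for a list test, and 2 of them rose and 1 fell.

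Across all genes edgeR called 5558 of 16544 between the fractions, 2909 higher and 2649 lower in the positive fraction, of which 716 and 537 differed at least 2-fold. Without the litter 3 libraries 6334 were called, 5020 of them the same genes. The 9 libraries of a fraction came from 3 litters, and the sort selected cells by reporter signal, so this comparison does not separate cell type from uptake of the vector.

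**Figure D3:**
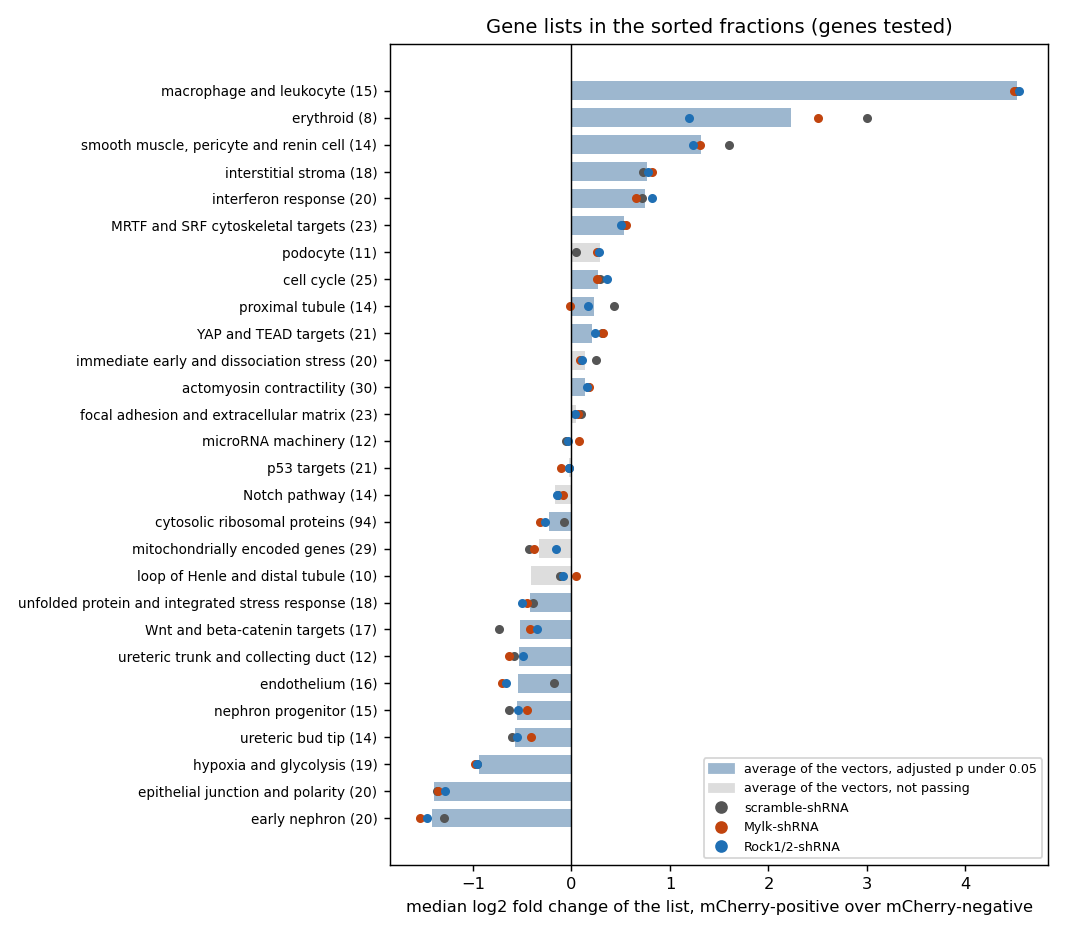
Median log2 fold change between the positive and negative fractions on the x axis for the 28 tested gene lists on the y axis (genes tested in parentheses); bars show the average over the vectors, blue where the camera test passed, and dots the medians of each vector. Macrophage and erythroid genes lie highest, with bars at 4.52 and 2.22, and early nephron and epithelial junction genes lowest, at -1.42 and -1.40.

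The fractions were also compared within each vector. With scramble-shRNA C1qc stood at 77.1 ± 17.6 against 0.537 ± 0.312 CPM, with Mylk-shRNA at 85.2 ± 27.3 against 1.04 ± 0.674 CPM and with Rock1/2-shRNA at 70.6 ± 14.7 against 1.16 ± 0.135 CPM (SD, n = 3 each). Macrophage genes rose in 14 of 15 cases with each vector (14 adjusted over the list alone). Their medians were 4.51, 4.50 and 4.54 (with an estimated correlation adjusted p = 0.000651, 0.000847 and 0.000467). Gpr15lg fell, with log2 fold changes of -3.79, -4.20 and -3.66, as did Lhx1 with -2.49, -2.89 and -3.12. Without scramble-shRNA positive or negative replicate 2, Lhx1 was not called with that vector (adjusted p = 0.0702 and 0.0560). Mylk was higher in the positive fraction by 1.46 ± 0.15 with scramble-shRNA, 1.19 ± 0.15 with Mylk-shRNA and 1.45 ± 0.15 with Rock1/2-shRNA (log2, SE). Stroma genes rose in 14, 15 and 15 of 18 cases (15, 16 and 16 adjusted over the list alone; with an estimated correlation adjusted p = 0.00303, 0.00186 and 0.00154). Early nephron genes fell in 12, 13 and 15 of 20 and rose in 1, 2 and 1 (17, 15 and 17 fell and 2, 2 and 2 rose adjusted over the list alone; 0.135, 0.152 and 0.0971). Hypoxia and glycolysis genes fell in 13, 17 and 16 of 19 cases (18, 19 and 19 adjusted over the list alone). The list test gave adjusted p = 0.0853, 0.0640 and 0.0508 with an estimated correlation and 0.00116, 0.000962 and 0.000501 when litter was also a block. Erythroid genes rose in 6, 5 and 2 of 8 cases (7, 7 and 2 adjusted over the list alone; medians 3.00, 2.51 and 1.20; with an estimated correlation adjusted p = 0.135, 0.180 and 0.455), and with Rock1/2-shRNA the call was lost with litter as a block (0.0643) and without litter 3 (0.309). Of 28 lists, 18, 19 and 20 passed with the preset correlation. Endothelial and cytosolic ribosomal genes did not pass with scramble-shRNA, nor did proximal tubule genes with Mylk-shRNA. With an estimated correlation 5, 5 and 4 lists held. Besides macrophage and stroma genes these were Wnt targets (adjusted p = 0.00721, 0.0103 and 0.0305 with an estimated correlation), the unfolded protein and integrated stress response (0.0297, 0.0280 and 0.0142) and, with scramble-shRNA and Mylk-shRNA, MRTF and SRF targets (0.0466 and 0.0487). When litter was also a block, the MRTF and SRF targets no longer held (0.0738 and 0.0899), nor did Wnt targets with Mylk-shRNA and Rock1/2-shRNA (0.0535 and 0.0848) or the stress response with Mylk-shRNA (0.0590), while ureteric bud tip genes held with scramble-shRNA (0.0392). With the preset correlation the block added focal adhesion and mitochondrially encoded genes for Mylk-shRNA (adjusted p = 0.0293 and 0.0331), both lost with an estimated correlation in that fit (0.563 and 0.719). Without litter 3, the calls of cell cycle genes with scramble-shRNA and of proximal tubule genes with Rock1/2-shRNA were lost (adjusted p = 0.0522 and 0.722). With 1 library left out, scramble-shRNA lost the calls of cell cycle genes in 2 of 6 fits and of ureteric trunk genes in 1, and Mylk-shRNA those of cell cycle genes in 2 and nephron progenitor genes in 1 (adjusted p up to 0.457, 0.105, 0.418 and 0.0699). Rock1/2-shRNA lost those of proximal tubule and erythroid genes in 3 each and of ureteric trunk and actomyosin genes in 2 each (0.507, 0.128, 0.0621 and 0.0577). Its proximal tubule median of 0.16 turned to -0.16 without Rock1/2-shRNA positive replicate 3 and -0.15 without litter 3, and its erythroid median there was 0.47.

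edgeR called 2032 genes with scramble-shRNA (1229 higher, 803 lower), 2186 with Mylk-shRNA (1335 and 851) and 1859 with Rock1/2-shRNA (1148 and 711). With litter as a block the counts were 3848, 4019 and 3369, and without litter 3 they were 2776, 2944 and 2013. Of 2972 genes called with at least 1 vector, 1242 were called with all 3 in the same direction, and none was called in opposite directions (by edgeR), where scramble-shRNA and Mylk-shRNA, for example, shared 956 higher genes against 99.2 for independent lists. Single libraries moved the counts: without scramble-shRNA negative or positive replicate 2 they fell to 1182 and 1184, without Mylk-shRNA positive replicate 1 to 1416, and without Rock1/2-shRNA positive or negative replicate 2 to 1167 and 1228.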

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

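Of the tests below, the bound on the targeted transcripts, the search for vector sequences, the comparison of macrophage with endothelial genes, the RNA quality shares of litter 3 and the comparison of each litter with the other 2 were chosen after the results were seen.

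The targeted transcripts were not called lower in the positive fraction. Too little precision to see a drop to 50% of scramble-shRNA is argued against, since the lowest of the 3 lower 95% bounds was 70.8% of scramble-shRNA. A different share of smooth muscle cells hiding such a drop of Mylk is argued against as well. With the mean of the smooth muscle genes as a covariate, the lower 95% bound of the log2 fold change of Mylk was -0.43. The estimate was -0.22, or 85.9% of scramble-shRNA against 87.9% without the covariate. The interval with the covariate, 74.2 to 99.4% of scramble-shRNA, held only values below scramble-shRNA. It thus gives a drop of Mylk smaller than one to 50%, without an adjustment over genes. Cells of the positive gate that carry no working cassette may still dilute a knockdown, which cannot be told apart here because the table names the vector or the reporter in 0 of its genes. A knockdown acting on protein more than on transcript was not tested.

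Macrophage and leukocyte transcripts were higher in the positive fraction, by a median log2 fold change of 4.52. A difference in depth is argued against, since thinning all libraries to 3121206 counts left a median of 4.26 or more in each of 3 draws. A lower share of epithelial cells would raise other cell types alike, and the macrophage median exceeded that of endothelium by 5.06, above the SD of 1.81 among its members. Autofluorescence of phagocytes, or their uptake of reporter from other cells, might place them in the gate without transduction, which cannot be told apart because 0 genes of the table stand for the vector. Transduction of macrophages by the virus is the biological explanation that stays open.

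The litter 3 libraries stood apart, with 5937 genes called between them and those of litters 1 and 2 by edgeR, a count that rests on 1 litter against 2 since correlated libraries of a litter were fitted as independent. Lower depth as the whole cause is argued against, since 4065 genes or more were called in each of 3 thinnings. RNA of lower quality or more nuclear RNA could account for part of it, which was not settled. The shares of mitochondrial genes and of unverified transcript models were both highest in litter 3 in 5 of 6 groups. These shares are part of the difference itself and were chosen after it was seen, so they cannot decide between such causes. Of the 3 litters set against the other 2, 1 gave as many genes, litter 3 itself, and the highest other gave 335, and 3 choices are too few for a share under 0.05. A difference between the litters' embryos, such as their exact stage, stays open and was not tested, though early nephron and nephron progenitor genes were lower in 12 of 20 and 9 of 15 cases and proximal tubule genes higher in 8 of 14, calls lost with an estimated correlation (adjusted p = 0.565, 0.570 and 0.565).

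For the counts of genes between fractions within 1 vector, 1 of 10 splits of the 6 libraries gave as many, the real one, with 2032 (scramble-shRNA), 2186 (Mylk-shRNA) and 1859 genes (Rock1/2-shRNA) against 0 in the highest other split of each by edgeR, and 10 splits are too few for a share under 0.05. For the average of the vectors 1 of 100 splits gave as many, the real one with 5558 genes, and the highest other gave 2817. This argues against a random division of the libraries. It gives no exact share for chance, since the other splits move the fraction difference into the spread between replicates, and libraries of a litter correlate. Among 39 other splits that part both fractions of every culture the highest gave 3422, and it differed from the real one by 1 swapped culture. The knockdown counts of 0 in both fractions, and those of 0 for both interactions (edgeR), are reached by any split, here 10 of 10 and 100 of 100, so these splits say nothing about chance. The highest other split of the knockdowns gave 1 gene, for Mylk-shRNA in the negative fraction, and those of the interactions gave 3 (Mylk-shRNA) and 0 (Rock1/2-shRNA).

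A difference of the knockdown effect between fractions was found by the interaction test for 8 lists, none of which held with an estimated correlation. With Mylk-shRNA the median interaction was 0.17 for nephron progenitor, -0.51 for proximal tubule, -0.41 for endothelial and -0.23 for cytosolic ribosomal genes. With Rock1/2-shRNA it was -0.49 for endothelial, -1.64 for erythroid, 0.11 for Wnt target and -0.17 for cytosolic ribosomal genes. Outside the genes tested, the ERCC spike-in transcripts, which no label mentions, held 338 counts over all libraries, 8 to 31 per library.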

How the results depend on the processing

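The fits without litter 3 and with the culture as a block were chosen after seeing the data. No alternative called a gene in the 5 knockdown comparisons or the 2 interactions by edgeR or DESeq2. At an unadjusted p under 0.05 edgeR gave 258 (Mylk-shRNA) and 145 genes (Rock1/2-shRNA) in the positive fraction, 199 between the knockdowns, 285 and 200 in the negative fraction, and 217 and 145 for the interactions, and DESeq2 gave 154, 79, 100, 219, 152, 138 and 90. The edgeR counts were 0.876 to 1.72% of genes, below the share of 0.05 that uniform p-values would give, so the fit without a block was conservative. With litter as a block edgeR gave 663, 352, 477, 1050, 644, 807 and 437 in the same order. The highest, for Mylk-shRNA in the negative fraction, was 6.35% of genes, with a smallest adjusted p of 0.235. Of the counts between fractions, the average of 5558 stayed within 1.5 times (4951 to 6037 with 1 library left out, 7569 with litter as a block, which shares 5556). With litter as a replicate block, the counts for scramble-shRNA, Mylk-shRNA and Rock1/2-shRNA were 3848, 4019 and 3369, and with the culture as a block 3466, 3674 and 3026. In fits to only the libraries of the compared groups the count for Mylk-shRNA was 1303, with fewer samples to estimate the spread. Leaving out 1 library gave 1182 to 2177 (scramble-shRNA), 1416 to 2438 (Mylk-shRNA) and 1167 to 1560 (Rock1/2-shRNA), and the cause of these shifts was not tested.

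Of the targeted transcripts, the log2 fold change of Rock1 in the positive fraction turned from -0.09 to 0.079 without litter 3, and lay between -0.17 and 0.052 with 1 library left out. Such ranges were -0.25 to -0.14 for Mylk and -0.24 to -0.06 for Rock2 in the positive fraction, and -0.041 to 0.21 for Mylk, -0.28 to -0.10 for Rock1 and -0.16 to 0.0075 for Rock2 in the negative fraction. None of these passed, and the cause was not tested.

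With the preset correlation 117 list tests passed (109 to 129 with 1 library left out). Of these, 19 held with an estimated correlation, 117 with DESeq2's size factors, 114 with litter as a block and 102 without litter 3. With 1 library left out, 869 of 990 calls held, 114 fell below the threshold and 7 turned the direction given by the camera test, over 42 and 4 lists (3, 1, 2 and 1 fits in the order below). Some left-out library moved the median over 1.5 times for 32 of 32 list calls of the knockdowns, 8 of 8 of the interactions and 15 of 77 between fractions. The median ranges of the 4 were -0.18 to 0.044 (cytosolic ribosomal, Rock1/2-shRNA, positive fraction), -0.22 to 0.049 (cell cycle, Mylk-shRNA, negative fraction), -0.13 to 0.27 (epithelial junction, Rock1/2-shRNA, negative fraction) and -0.042 to 0.25 (cytosolic ribosomal, Rock1/2-shRNA, negative fraction). Counted by the sign of the median, some left-out library turned 7 of the 32 knockdown calls and 1 of the 77 between fractions. Besides the 4, these were erythroid, cell cycle and ribosomal genes between the knockdowns and proximal tubule genes between fractions with Rock1/2-shRNA. The cause was not tested.  The block changed no other list call than those given with the results. By limma's fry, 20 of 28 lists passed at an adjusted p under 0.05 in the average of the vectors. Within scramble-shRNA, Mylk-shRNA and Rock1/2-shRNA fry passed 17, 17 and 16 lists, and in each knockdown comparison and interaction 0. Of 119 further results of genes named in the report, called or not, Hnf4a in the average of the vectors and Lhx1 with scramble-shRNA lost their call without some library, and Lhx1 also without a filter on low counts. Rock2 in the average of the vectors, not called in the fit as reported, was called with litter or the culture as a block and without litter 3, or without scramble-shRNA positive replicate 3 or Mylk-shRNA negative replicate 2 alone. The Rock2 interaction with Rock1/2-shRNA, which did not pass, ranged from -0.18 to 0.022 with 1 library left out, and the cause was not tested.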

Other observations

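The gene lists in these observations, and the genes named from them, were chosen after the values were seen, and the comparison of litter 3 with the other litters was likewise chosen afterwards. Genes of lysosomes and phagocytes rose in the positive fraction in 15 of 17 cases, with a median log2 fold change of 1.04 (average of the vectors; camera, adjusted p = 6.40e-31, and 0.00320 with an estimated correlation). Gpnmb, named before, stood highest (6.60), followed by the cathepsin gene Ctss (5.70), with Trem2, a receptor of phagocytes, at 5.36, Gas6, a bridging ligand for apoptotic cells, at 2.08 and its receptor gene Mertk at 1.39. The broadly expressed lysosomal genes Ctsb (1.23), Ctsd (1.21), Grn (1.06), Hexa (0.86) and Psap (0.84) rose less, and Lamp2 (0.11) was among those that did not pass. Transcription factor genes of the nephron lineage fell in 9 of 9 cases, with a median of -2.02 (adjusted p = 2.17e-09, and 0.0715 with an estimated correlation). Besides Lhx1 they included Osr2 (-2.44), Emx2 (-2.14), Pax8 (-2.05), Pou3f3 (-1.37), Dach1 (-1.22), Elf3 (-1.18) and Pax2 (-1.09). Lhx1, Osr2, Emx2, Pax8 and Pou3f3 are also members of the early nephron list, so this fall in part repeats the result of that list.

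Genes for entry of adeno-associated virus did not part the fractions as a list (2 of 12 higher and 3 lower, 2 and 4 adjusted over the list alone, median 0.02, adjusted p = 0.685). AU040320, the receptor gene used by most serotypes, stood at 17.2 ± 2.58 CPM in the positive and 17.1 ± 2.55 CPM in the negative fraction (SD, n = 9 each). The proteoglycan gene Sdc3 (0.48) and the heparan sulfate enzyme gene Ndst1 (0.28) rose, while Sdc4 (-0.78), the receptor gene Met (-0.66) and Sdc2 (-0.46) fell. A list of RNAs retained in the nucleus did not part the fractions either (0 of 6 called by edgeR, median -0.27, adjusted p = 0.685).

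The libraries of litter 3 and of litters 1 and 2 were fitted as independent although those of a litter correlate, so the p-values below rest on 1 litter against 2. Between them, mitochondrially encoded genes were higher in 26 of 29 cases, with a median of 1.24 (camera, adjusted p = 4.92e-17, and 0.273 with an estimated correlation), such as mt-Nd1 (1.51). Cell cycle genes were lower in 23 of 25 cases with a median of -0.34 (adjusted p = 8.30e-11, and 0.273 with an estimated correlation), such as Top2a (-0.47) and Mki67 (-0.32), and hypoxia and glycolysis genes in 12 of 19 with a median of -0.31 (adjusted p = 0.273 with an estimated correlation), such as the glucose transporter gene Slc2a1 (-0.68). Of the 6 RNAs retained in the nucleus 5 were higher, Rn7sk (1.84), Kcnq1ot1 (1.70), Malat1 (1.49), Neat1 (1.30) and Meg3 (1.29), and Xist did not pass (0.082, adjusted p = 0.952). The value of Xist joins unlike cultures of litter 3, at 3.92 and 1.71 CPM with Rock1/2-shRNA and 252 to 376 CPM with the other vectors. In litters 1 and 2 it ranged from 85.2 to 253 CPM. Early nephron (12 of 20 lower, median -0.56, adjusted p = 0.000168), nephron progenitor (9 of 15, -0.24, 0.00825), epithelial junction (10 of 20, -0.59, 0.00169), Notch pathway (7 of 14, -0.37, 0.000168) and focal adhesion genes (13 of 23, -0.24, 0.00884) were lower as lists. Proximal tubule (8 of 14 higher, 0.53, 0.000642), interferon response (5 of 20, 0.33, 0.0380) and cytosolic ribosomal genes (51 of 94, 0.25, 1.12e-10) were higher. No list held with an estimated correlation there (adjusted p = 0.273 to 0.570 for these).

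In the Rock1/2-shRNA culture of litter 3, Xist, which is expressed from the inactive X chromosome, stood at 3.92 CPM in the positive and 1.71 CPM in the negative fraction, and Y-linked genes summed to 167 and 179 CPM. In the other 16 libraries Xist ranged from 85.2 to 376 CPM. Y-linked genes summed to 40.5 and 49.8 CPM in the positive and negative fraction of the Rock1/2-shRNA culture of litter 1, 24.5 and 22.6 CPM in that of litter 2, and 73.9 to 157 CPM in the 12 libraries of the other vectors. The Rock1/2-shRNA cultures thus differed from the others in Y-linked transcripts in each litter, and sex was not a term in any fit. Comparisons of Rock1/2-shRNA with another vector, and its interaction, therefore do not separate this difference from the vector.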
